A study of Homo sapiens with 2 samples.

How the data were processed

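Each of the 2 samples was a 2-colour array that held RNA of U937 cells with a miR-194-5p vector treated with MS-275 (5 µM, 24 h) and RNA of the same cells left untreated. Per the labels, the arrays were biological replicates 1 and 2, and the treated RNA was labelled with Cy5 on the first and Cy3 on the second. Per the labels' protocols, total RNA was extracted with Trizol and labelled with a linear amplification kit together with spike-in RNAs.

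The authors scanned the arrays and extracted spots with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers. The deposited scanner files give, per the file headers, the median pixel intensity and the median local background intensity of each spot in green (Cy3) and red (Cy5). They also give flags for spots well above background, saturated or not uniform. Per the file headers, they hold a log10 ratio of red over green that the software made from background-subtracted, dye-normalized signals before the files were deposited. The deposited value table held the natural log of treated over untreated RNA in both columns. Its scale and direction were found by comparison with the scanner values: over 4095 bright probes its spread was 0.697 and 0.703 times that of the log2 ratios, where a natural log gives 0.693, and r was 0.997 and 0.999. The medians of its columns were -0.024 and -0.08, and its background treatment and centring stay unknown.

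The array held 45015 spots, 1639 of them controls, for 41000 probes. Median signals of gene spots were 86 and 125 in green and 252 and 268 in red, over median backgrounds of 39 and 39 in green and 145 and 144 in red. In the file headers, the observed log ratios of the spike-in RNAs had a slope of 0.8897 and 0.9526 against the expected ones, a compression of the software's own log ratios. The ratios used here are compressed further by the offset of the background correction: the largest was 5.56 on the log2 scale, against 6.39 with an offset of 10. It was 8.17 with the software's log ratio, which differs in background and dye treatment as well, and 5.29 with no background correction. The scanner flags marked 149 and 268 gene spots as outliers, and these were left out. No spot was saturated (0 on each array). Both arrays lay on 1 slide of 1 scan, so that no batch was to be tested.

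From the median intensities, the local background was corrected with normexp (offset 50) and log2 ratios were normalized by loess within each array, with control and outlier spots at weight 0 (R 4.3.3, limma 3.58.1). The plan written before the data were examined named the mean pixel intensity, and the median was used, since it is what these files give for the spots. The ratio of replicate 2 was turned so that positive values mean more treated RNA. Spots of a probe were averaged. A probe was kept where the treated RNA or the untreated RNA was well above background on both arrays, which left 20291 probes. A gene that is dim in the untreated RNA therefore entered only where its treated RNA was bright, and the reverse, so that in lists with many dim members the filter favours members that changed. The brightest probe stood for its gene. A gene for which 1 RNA was not well above background on either array is given as "at least N-fold". This bound is the mean level of the bright RNA over the mean of, per array, the higher of the lowest level well above background and the gene's own, after loess and quantile scaling of the average intensities. The adjusted p of a gene given as a bound comes from the same fit as all others. Where the gene's own level is the higher on both arrays, the bound equals the measured ratio, as for CCL4 and PDGFRB. Each bound is on the mean ratio of the 2 arrays and carries no spread, and the ratio of a single array can lie below it.

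Probes were named through their accessions, without versions, in a RefSeq gene table for GRCh38.p14. Of 41000 probes 23958 were matched and 17042 kept the name in the file. The array annotation is for hg18, so no coordinates are given, and the table served only for names and for the order of genes. Of 535 symbols in the lists, 16 had no named probe. Among the 1239 genes called, 220 had several probes, and in 5 of these the probes differed in sign.

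The mean log2 ratio was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment over all 15966 genes and a threshold of 0.05. The fit had 1 residual degree of freedom and 8.56 prior degrees of freedom, so that the spread of each gene was drawn mostly from all genes. A dye term would have used the residual degree of freedom, and a dye effect therefore cancels in the mean and stays in the spread. Across 28 gene lists written before the data were examined, those with at least 5 tested genes were tested with camera (preset correlation 0.01), with an estimated correlation and with fry. With 2 arrays, an estimated correlation rests on 1 degree of freedom. In simulation, a shifted list of 15 genes had p = 3.2e-29 with the preset and p = 0.15 with the estimated correlation. Random lists passed unadjusted in 3.4% of 500 simulated draws and in 2.6% of draws from the data. The simulated genes were independent and the lists were random, so these rates do not test the preset on genes that move together. Among the lists called, the estimated correlation ran from -0.2 for erythroid and megakaryocyte markers to 0.733 for MHC class II.

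The gene test was tested on simulated data for the comparison of treated with untreated RNA over 15966 genes. With 200 changed genes it recovered 8.82%, 83.3% and 100% of changes of 1, 2 and 3 on the log2 scale, with 10.6% false calls. With 4000 changed genes it recovered 39.7%, 97.8% and 100%, with 3.59% false calls.

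The text names the 12 largest increases and the 12 largest decreases among genes with a symbol that passed the test and were at least 2-fold changed the same way on both arrays. It also names up to 4 members of each list past the test, or the 2 farthest from 0 where none passed, and CDKN1A, TNFSF10, BCLAF1, HDAC1, HDAC2, HDAC3 and MYC. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here. The alternatives were no background correction, an offset of 10, median centring, the scanner software's log ratio, the value table, no filter, both RNAs above background, the mean of all probes, no saturated probes, a trended robust prior, a 1.5-fold threshold, the other list tests and each array alone. Testing only genes with a current symbol was added after the data were seen.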

Results

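U937 is an established human monocytic leukaemia cell line. The cells studied here carried a vector for the microRNA miR-194-5p, and they were treated for 24 h with 5 µM MS-275 (entinostat), an inhibitor of class I histone deacetylases, or left untreated. The comparison asks which transcripts MS-275 changed in these cells. Treated and untreated RNA were hybridised together on 2-colour whole-genome oligonucleotide arrays, 1 array for each of 2 biological replicates. The treated RNA carried Cy5 on the array of replicate 1 and Cy3 on that of replicate 2, so that the dyes were swapped. Of 41000 probes, 59.7% (replicate 1) and 42.6% (replicate 2) were well above background in the treated RNA, and 48.2% and 56.1% in the untreated RNA. After filtering, 15966 genes were tested, of which 10063 had a current symbol. The number of arrays limits the precision of every value. Cells without the vector were not analysed here.

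The largest increase after MS-275 was that of S100A8, a calcium-binding alarmin of monocytes and neutrophils, with a mean log2 ratio of treated over untreated RNA of 5.56 ± 0.32 (SD, n = 2). SPP1, which encodes the secreted matrix protein osteopontin, rose at least 41.2-fold, and KRT23, a type I keratin, rose at least 35.2-fold. These bounds are on the mean of the 2 arrays. The log2 ratios on replicates 1 and 2 were 4.94 and 6.07 for SPP1 and 4.39 and 6.465 for KRT23. CCR7, a chemokine receptor that guides leukocytes to lymph nodes, rose by 5.19 ± 0.39 on the log2 scale, and GZMA, the granule protease granzyme A of cytotoxic lymphocytes, by 4.95 ± 0.57. Among genes with a symbol, the largest decrease was that of CLEC2B, a C-type lectin, at -3.53 ± 0.17. Next came RGL4, a relative of the exchange factors of the GTPase Ral, at -3.22 ± 0.26. Over all genes tested the lowest ratio was -3.68, for an entry without a symbol. CARD9, an adaptor in antifungal signalling, changed by -2.79 ± 0.39, and PNP, the purine salvage enzyme purine nucleoside phosphorylase, by -2.61 ± 0.50.

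Among the other largest increases, EMP1, a tetraspan membrane protein, changed by 5.19 ± 0.96 and TEX19, a gene best known from germ cells, by 5.12 ± 0.58. LGALS2, a galectin, changed by 4.98 ± 1.23, GRAMD1C, a sterol transport protein, by 4.88 ± 0.58, and HLA-DPA1, an MHC class II chain, by 4.67 ± 1.27. EFNB2, the Eph receptor ligand ephrin-B2, rose at least 26.6-fold, and SELENOP, a selenium transport protein, rose at least 19.3-fold. The other largest decreases were PPP1R16A, a regulatory subunit of protein phosphatase 1, at -2.85 ± 0.85, CCDC86, a nucleolar protein, at -2.78 ± 0.61, and PLD6, a mitochondrial phospholipase, at -2.77 ± 0.77. LRFN4, an adhesion protein, changed by -2.70 ± 0.58, MRM1, a mitochondrial rRNA methyltransferase, by -2.61 ± 0.75, and IL18RAP, a subunit of the interleukin-18 receptor, by -2.59 ± 0.40. LGALS12, a galectin, changed by -2.55 ± 0.28 and ATAD3A, a mitochondrial membrane ATPase, by -2.53 ± 0.73. All of these genes changed the same way on both arrays, as the rule that chose them requires, with adjusted p between 2.68e-04 for CCR7 and 0.00382 for ATAD3A. The untreated RNA of S100A8 and EMP1 was well above background on 1 of the 2 arrays. Second probes gave 1.82 for HLA-DPA1, -1.08 for PPP1R16A and -2.03 for CCDC86.

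**Figure D1:**
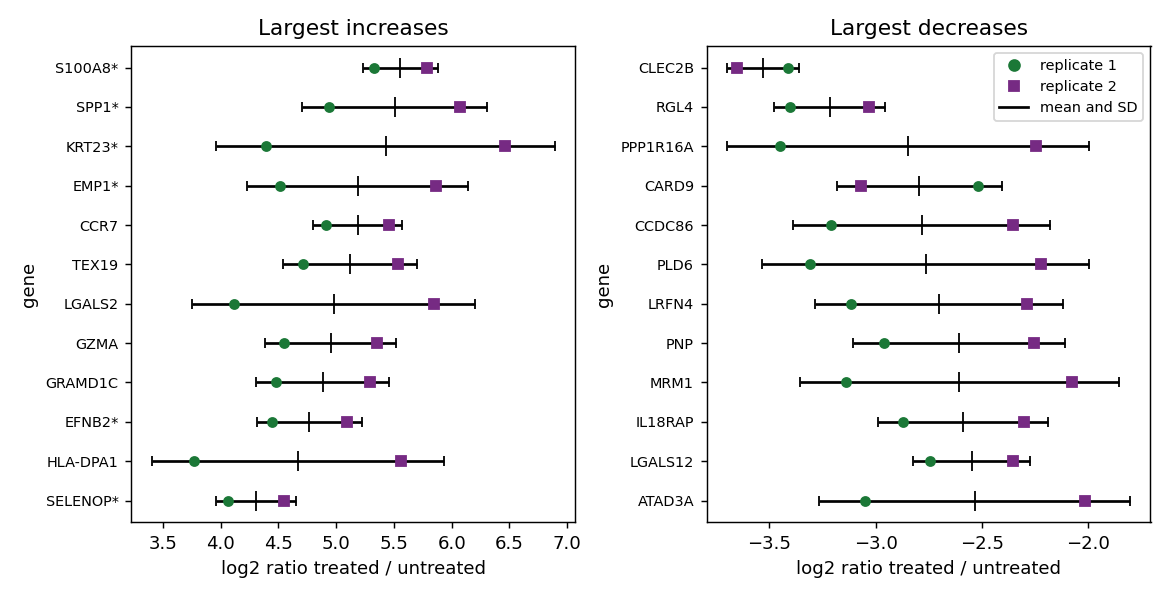
Log2 ratio of treated over untreated RNA for the 12 largest increases (left) and the 12 largest decreases (right) among named genes past the test, with circles for replicate 1, squares for replicate 2 and the mean with its SD as a bar. Asterisks mark genes whose untreated RNA was well above background on fewer than 2 arrays, and the mean ran from 5.56 for S100A8 to -3.53 for CLEC2B.

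In all, 824 genes rose and 415 fell (limma, Benjamini-Hochberg adjusted p under 0.05), 7.76% of the genes tested, and all 1239 changed the same way on both arrays. With 2 arrays, a gene with opposite signs could not pass this test, so the shared direction of the calls is no measure of agreement. Of the genes called, 601 that rose and 326 that fell had a symbol, and the others were tested under the name in the file. Increases made up 66.5% of the calls. That share was 62.8% when only genes with a symbol were tested (695 higher and 411 lower). It was 54.6% with the log ratio of the scanner software, 55.9% with the deposited value table and 59.2% among genes with both RNAs above background. At an unadjusted p under 0.05, 2052 genes were higher and 1777 lower. That direction turned with the scanner software's log ratio, 2152 higher and 2646 lower, and with the deposited values, 1904 higher and 2278 lower. It held with no background correction (1991 and 1740) and an offset of 10 (2125 and 1858). Among genes with both RNAs above background, 1519 were higher and 1507 lower. Under the chosen settings, 918 genes were at least 2-fold higher on both arrays and 473 at least 2-fold lower, against 58 that were at least 2-fold changed in opposite directions. Across genes, which are not independent replicates, the log2 ratios of the arrays correlated with r = 0.595 (Spearman rho = 0.496), and with r = -0.595 before the dye swap was turned. The median SD between replicates was 0.34 on the log2 scale, against 0.18 and 0.21 between repeated spots of 264 probes on the same array. The SD between replicates rests on 2 values per gene and holds any dye effect, and the prior SD of the fit was 0.487. The smallest change called was 2.36-fold. Of the genes that rose, 162 (19.7%) had untreated RNA that was not well above background on either array. With median centring in place of loess, 6 genes rose and 0 fell by limma, with 219 and 23 at an unadjusted p under 0.05.

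**Figure D2:**
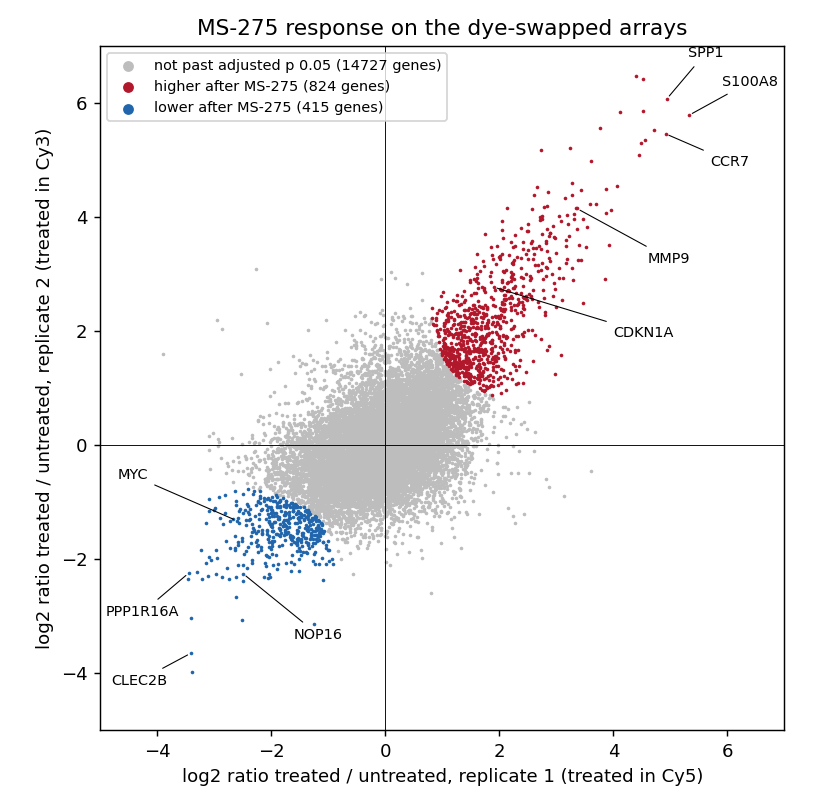
Log2 ratio of treated over untreated RNA of each of the 15966 genes tested, replicate 1 on the x axis and replicate 2 on the y axis, with the 824 genes that rose in red, the 415 that fell in blue and the others in grey. All coloured genes lie in the quadrants where both arrays changed the same way, which the test with 2 arrays requires, and r across genes was 0.595.

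Genes described as responding to class I histone deacetylase inhibitors rose as a group. DHRS2, a short-chain dehydrogenase, changed by 3.38 ± 0.30, CDKN1A, the CDK inhibitor p21, by 2.34 ± 0.62 (adjusted p = 0.00488), and BMF, a pro-apoptotic BH3-only protein, by 2.04 ± 0.94. Of 13 tested genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone, 8 and 0 at an unadjusted p under 0.05), with a median log2 ratio of 1.17 and adjusted p = 1.33e-05 by camera with a preset correlation (adjusted p = 0.847 with an estimated correlation). The second probe of DHRS2 gave 4.71 and that of CDKN1A 1.02. CDK inhibitors and growth arrest genes also rose, led by CDKN1A, by BTG1, an antiproliferative factor, at 2.31 ± 0.81, by GADD45A, a stress and growth arrest gene, at 2.06 ± 0.27, and by CDKN2D, the CDK4 and CDK6 inhibitor p19, at 1.99 ± 0.59. Here 7 rose and 0 fell (8 and 0 adjusted over the list alone, 8 and 0 at an unadjusted p under 0.05) of 15 tested genes, with a median of 1.05 and adjusted p = 0.00100 (adjusted p = 0.847 with an estimated correlation). The median was 0.33 over the 13 of these genes with both RNAs above background, 0.69 with no filter on dim probes and 2.07 with the log ratio of the scanner software, and the list stayed past the threshold under each.

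The transcripts of the deacetylases that MS-275 inhibits did not pass the test. HDAC1 had a log2 ratio of 0.12 ± 0.82, HDAC2 of 0.18 ± 0.69 and HDAC3 of 0.18 ± 0.63, each with opposite signs on the 2 arrays. Of 16 tested deacetylase genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, 2 and 2 at an unadjusted p under 0.05), and the gene that rose was SIRT4, a mitochondrial sirtuin, at 1.54 ± 0.58. The list had a median of -0.12 (-0.35 on replicate 1 and 0.095 on replicate 2) and adjusted p = 0.772. All 25 tested histone genes had a positive mean ratio, with a median of 0.54, and the list shifted up with adjusted p = 6.29e-04 (adjusted p = 0.858 with an estimated correlation). Of these, 1 rose and 0 fell (1 and 0 adjusted over the list alone, 7 and 0 at an unadjusted p under 0.05). The median of the list was 0.99 on replicate 1 and 0.09 on replicate 2, and probes for histone genes of the same cluster can share signal.

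MYC, the transcription factor that drives cell growth, fell, with a log2 ratio of -1.96 ± 0.90 (adjusted p = 0.0155), and genes of ribosome biogenesis fell with it. NOP16, a nucleolar protein, changed by -2.37 ± 0.17, PPAN, a factor of large ribosomal subunit assembly, by -2.26 ± 0.65, RRP12, an export factor of ribosomal subunits, by -2.09 ± 0.03, and RRS1, a regulator of ribosome synthesis, by -1.995 ± 0.34. Of 22 tested genes of the list, which holds MYC itself, 0 rose and 11 fell (0 and 16 adjusted over the list alone, 0 and 16 at an unadjusted p under 0.05), with a median of -1.46 and adjusted p = 8.76e-12 (adjusted p = 0.847 with an estimated correlation). A second probe of PPAN gave -0.30, and with the mean of its probes, -1.28, PPAN did not pass the test.

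Of 30 DNA replication genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone, 0 and 4 at an unadjusted p under 0.05): MCM5 at -1.61 ± 0.67 and MCM7 at -1.51 ± 0.04, both subunits of the replicative helicase. The list had a median of -0.18 (-0.44 on replicate 1 and -0.12 on replicate 2) and adjusted p = 0.119, which was 0.0252 with no filter on dim probes and up to 0.26 under the other alternatives with the preset correlation. Of 28 mitosis genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, 3 and 3 at an unadjusted p under 0.05), and CDK1, the kinase that drives entry into mitosis, was the gene that rose, at 1.40 ± 0.30. The mitosis list had a median of 0.28 (0.093 on replicate 1 and 0.29 on replicate 2) and adjusted p = 0.391. Among 16 genes of homologous recombination repair, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 1 at an unadjusted p under 0.05) by limma, the median was -0.05 (-0.23 on replicate 1 and 0.24 on replicate 2) and adjusted p was 0.799. The members farthest from 0 were FANCG, a Fanconi anaemia core protein, at -0.82 ± 0.02, and RAD54B, a recombination helicase, at 0.70 ± 0.06, and neither passed the test.

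In the death receptor pathway, TNFSF10, which encodes the death ligand TRAIL, rose by 1.60 ± 0.08 (adjusted p = 0.0178), and its receptors TNFRSF10B and TNFRSF10C, the latter a decoy, by 1.97 ± 0.42 and 1.39 ± 0.32. A second probe of TNFRSF10B gave 0.65, and the untreated RNA of TNFRSF10C was above background on 1 array. Of 12 tested genes, 3 rose and 0 fell (3 and 1 adjusted over the list alone, 3 and 1 at an unadjusted p under 0.05). The list median was -0.07 (-0.16 on replicate 1 and 0.14 on replicate 2) while its mean was 0.26 and its test pointed up, with adjusted p = 0.516. Of 12 pro-apoptotic BCL2 family genes, 2 rose and 0 fell (3 and 2 adjusted over the list alone, 5 and 4 at an unadjusted p under 0.05): BMF, and BNIP3L, a mitophagy receptor, at 1.42 ± 0.20. A second probe of BNIP3L gave 0.86, and with the mean of both probes, 1.14, BNIP3L did not pass the test. The list had a median of 0.10 (0.18 on replicate 1 and 0.20 on replicate 2) and adjusted p = 0.735. Of 11 survival genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone, 2 and 2 at an unadjusted p under 0.05). BIRC3, an inhibitor of apoptosis protein, changed by 1.84 ± 0.11 and AVEN, a caspase activation inhibitor, by -2.03 ± 0.19, with a list median of -0.21 (0.15 on replicate 1 and -0.22 on replicate 2) and adjusted p = 0.843.

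Monocyte and macrophage markers rose as a group. Beside S100A8, they included MMP9, the gelatinase of migrating phagocytes, at 3.75 ± 0.56, S100A9, the partner of S100A8, at 3.36 ± 0.91, and CD163, the haemoglobin scavenger receptor of macrophages, which rose at least 8.83-fold. Of 20 tested genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, 12 and 1 at an unadjusted p under 0.05), with a median of 1.73 and adjusted p = 3.04e-09 (adjusted p = 0.847 with an estimated correlation). The median was 0.65 over the 14 of these genes with both RNAs above background and 0.52 with no filter on dim probes, which takes in 27 genes, and the list stayed past the threshold under both. The untreated RNA of S100A9 was above background on 1 array. Granule and neutrophil genes went both ways: of 9 tested, 1 rose and 1 fell (3 and 2 adjusted over the list alone, 3 and 2 at an unadjusted p under 0.05). CAMP, the antimicrobial peptide cathelicidin, changed by 3.96 ± 0.37 and CEBPE, a transcription factor of granulocyte maturation, by -1.54 ± 0.93. The list median was -0.37 (-0.78 on replicate 1 and 0.19 on replicate 2) and its test pointed down while its mean was 0.23, with adjusted p = 0.899.

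Among 19 myeloid progenitor and leukaemia regulators, 4 rose and 0 fell (5 and 1 adjusted over the list alone, 5 and 1 at an unadjusted p under 0.05). KLF2, a transcription factor of quiescent immune cells, rose at least 11.7-fold, and EGR2, a zinc finger factor of macrophage differentiation, rose at least 12.1-fold. CEBPB and KLF4, both transcription factors of monocyte differentiation, changed by 1.89 ± 0.89 and 1.37 ± 0.47. A second probe of CEBPB gave 0.76, and with the mean of its probes, 1.33, CEBPB did not pass the test. The list had a median of 0.13 (-0.31 on replicate 1 and 0.29 on replicate 2) and adjusted p = 0.422.

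The MHC class II list, whose genes present antigen to T cells, had the highest median of all lists, 2.40 (3.63 with the log ratio of the scanner software). Beside HLA-DPA1, HLA-DMB, a chain of the peptide exchange factor, changed by 3.95 ± 0.74, HLA-DRB5 by 3.72 ± 0.34 and HLA-DRB1 by 3.39 ± 0.63. The probes of HLA-DRB1 and HLA-DRB5 can share signal. Of 15 tested genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, 13 and 0 at an unadjusted p under 0.05), with adjusted p = 7.51e-13 (adjusted p = 0.847 with an estimated correlation). Interferon response genes rose too, among them IFIT2 and IFIT1, antiviral proteins of the same family, at 3.08 ± 0.04 and 3.06 ± 0.24. ISG20, an exonuclease, changed by 2.48 ± 0.27 and OASL, a relative of the oligoadenylate synthetases, by 2.40 ± 0.79. Of 24 tested genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone, 11 and 1 at an unadjusted p under 0.05), with a median of 0.67 and adjusted p = 0.00112 (adjusted p = 0.847 with an estimated correlation). The fifth gene that rose was IFI44, at 1.69 ± 0.75, and the one that fell was MX2, an antiviral GTPase, at -1.35 ± 0.23, both chosen after their values were seen.

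Of 14 inflammatory cytokine and NF-kB genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, 4 and 2 at an unadjusted p under 0.05). CCL2, the monocyte chemoattractant, changed by 2.93 ± 0.48, IL1B, interleukin-1 beta, by 2.51 ± 0.05, and CCL4, a chemokine, rose at least 3.97-fold. TNFAIP3, a brake on NF-kB signalling that was chosen after its value was seen, changed by 1.56 ± 0.66. CXCL2, a neutrophil chemoattractant, was the gene that fell, at -1.68 ± 0.26. Its second probe gave -0.62, and with the mean of both probes, -1.15, it did not pass the test. The list had a median of 0.25 and adjusted p = 0.177.

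Cholesterol synthesis genes shifted up by a narrow margin, with a median of 0.47 and adjusted p = 0.0456 (adjusted p = 0.847 with an estimated correlation), a call that held in 3 of 9 alternatives with the preset correlation. The median was 0.24 on replicate 1 and 0.45 on replicate 2. Of 19 tested genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, 6 and 0 at an unadjusted p under 0.05): SQLE, squalene epoxidase, at 1.64 ± 0.76, and HMGCS1, the cytosolic HMG-CoA synthase, at 1.41 ± 0.41. Of 10 metallothioneins, which bind zinc and copper and whose probes can share signal, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 2 and 0 at an unadjusted p under 0.05) by limma. Their median was 1.32 on replicate 1 and -0.10 on replicate 2, with adjusted p = 0.158, and MT1X and MT1B had means of 0.99 ± 1.40 and 0.99 ± 0.90. Of 19 unfolded protein and heat shock genes, 0 rose and 1 fell (0 and 6 adjusted over the list alone, 1 and 7 at an unadjusted p under 0.05), the gene past the test being HSPH1, a heat shock chaperone, at -1.70 ± 0.57. That list had a median of -0.26 (-0.54 on replicate 1 and -0.17 on replicate 2) and adjusted p = 0.119, which was 0.0246 with no filter on dim probes and up to 0.284 under the other alternatives with the preset correlation.

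Of 22 lysosomal genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone, 7 and 0 at an unadjusted p under 0.05). CTSL, the protease cathepsin L, changed by 2.58 ± 0.03, with untreated RNA above background on 1 array. The list had a median of 0.27 (-0.0044 on replicate 1 and 0.41 on replicate 2) and adjusted p = 0.124. Of 10 neuronal genes under control of the repressor REST, 2 rose and 0 fell (3 and 0 adjusted over the list alone, 3 and 0 at an unadjusted p under 0.05): CHGB, the secretory granule protein chromogranin B, at 2.60 ± 1.03, and STX1A, a synaptic syntaxin, at 1.27 ± 0.34 (adjusted p = 0.0499). A second probe of CHGB gave 1.32. The list median was -0.15 (-0.19 on replicate 1 and 0.25 on replicate 2), while its mean was 0.40 and its test pointed up, with adjusted p = 0.391.

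Of 10 genes described as targets of miR-194-5p, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 2 and 1 at an unadjusted p under 0.05) by limma, with a median of 0.30 (0.28 on replicate 1 and -0.20 on replicate 2) and adjusted p = 0.843. BCLAF1, a described target that regulates apoptosis and transcription, had a ratio of -0.65 ± 0.01 (adjusted p = 0.265), and its 3 probes ran from -0.65 to 0.32. The members farthest from 0 were BMI1, a polycomb protein, at -1.11 ± 0.05, and IGF1R, a growth factor receptor, at 0.88 ± 0.41, and neither passed the test. Both RNAs came from cells with the vector, so the values compare MS-275 with no treatment and not the microRNA with its absence. Whether MS-275 changed the level of the microRNA, or the response depends on it, was not tested here.

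Markers of other cell types were mostly below background. Of 15 T and B cell markers with a probe 4 were tested, of which 1 rose and 0 fell (1 and 1 adjusted over the list alone, 1 and 1 at an unadjusted p under 0.05), the gene that rose being CD2, an adhesion receptor of T and natural killer cells, at 2.56 ± 0.67. Of 17 erythroid and megakaryocyte markers with a probe 5 were tested, and 4 of the 5 entered the test only through the treated RNA, 3 of them with untreated RNA that was not above background on either array. Of the 5, 3 rose and 0 fell (5 and 0 adjusted over the list alone, 5 and 0 at an unadjusted p under 0.05), with adjusted p = 1.05e-04 (adjusted p = 0.847 with an estimated correlation) and a median of 1.39. With no filter on dim probes, which takes in all 17, the median was 0.064 and adjusted p = 0.0495, and with other scalings the median reached 3.49. The genes that rose were all globins, whose probes can share signal: HBB rose at least 5.04-fold, HBG1 rose at least 2.62-fold, and HBD changed by 2.12 ± 0.07. The untreated RNA of CD2 and HBD was above background on 1 array. Of 13 fibroblast and endothelial markers with a probe 4 were tested, of which 1 rose and 0 fell (2 and 0 adjusted over the list alone, 2 and 0 at an unadjusted p under 0.05), and PDGFRB, a growth factor receptor, rose at least 2.42-fold. Of 12 epithelial markers with a probe 3 were tested, of which 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 0 at an unadjusted p under 0.05) by limma, with KRT18 at 0.70 ± 0.48 and KRT8 at -0.44 ± 0.65. Of 15 housekeeping genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, 1 and 0 at an unadjusted p under 0.05): B2M, the light chain of MHC class I, at 1.42 ± 0.56. The housekeeping list had a median of -0.38 (-0.32 on replicate 1 and 0.058 on replicate 2) and adjusted p = 0.657.

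**Figure D3:**
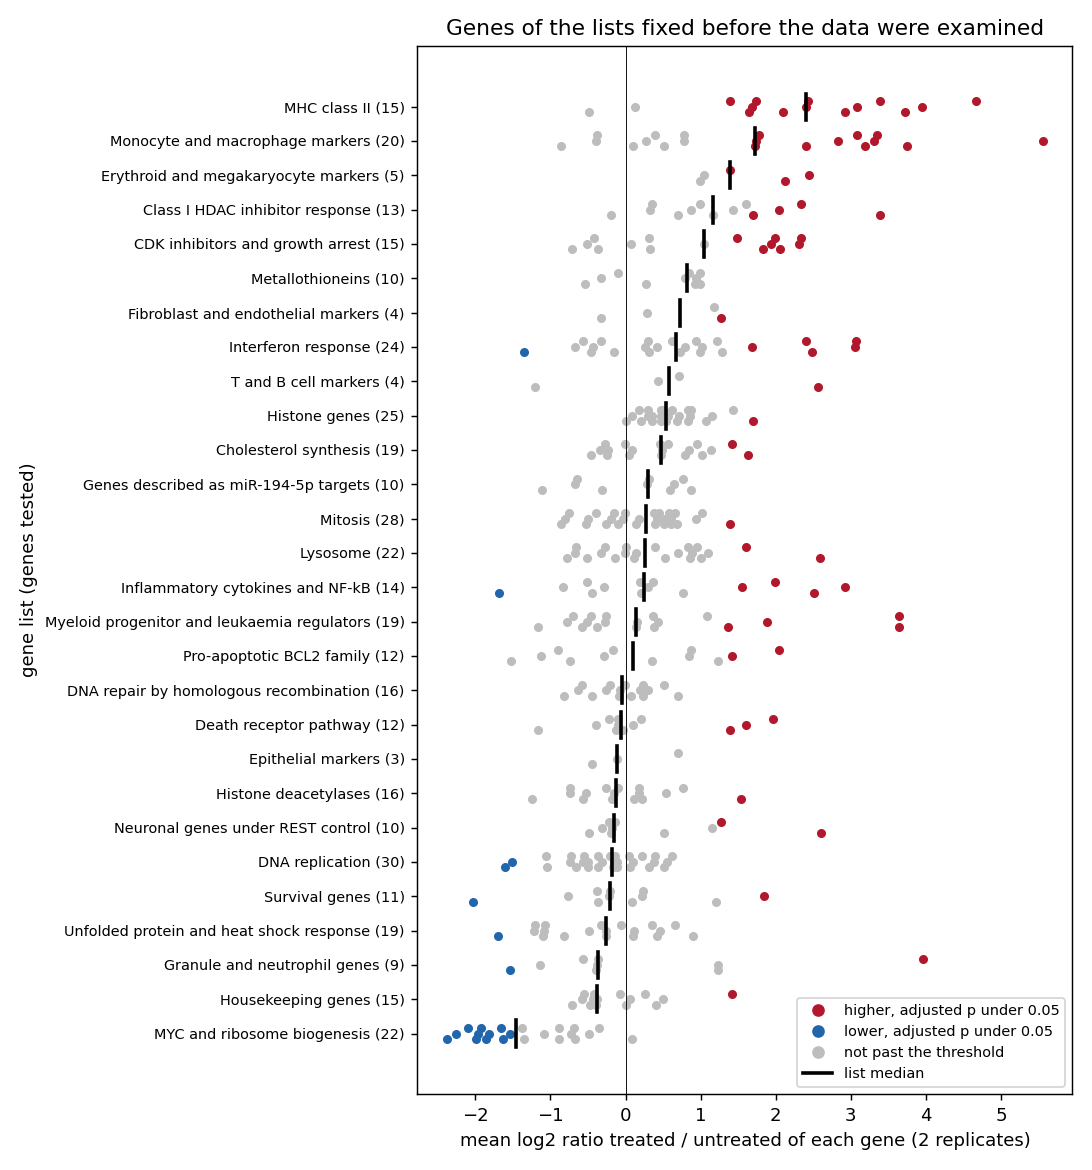
Mean log2 ratio of treated over untreated RNA (2 replicates, x axis) of each tested gene in the 28 lists fixed before the data were examined (y axis), red for genes that rose, blue for genes that fell, grey for genes not past the threshold, and a black line for each list's median. The medians ran from 2.40 for MHC class II to -1.46 for MYC and ribosome biogenesis.

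Of the 25 lists with at least 5 tested genes, 9 shifted by camera with a preset correlation, 8 up and 1 down. With the correlation estimated from the 2 arrays, camera called 0 lists, and 0 at an unadjusted p under 0.05, the smallest p being 0.0924. By fry, 0 lists passed after adjustment and 3 at an unadjusted p under 0.05.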

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

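Testing only genes with a symbol was chosen after the data were seen, and the other alternatives before. No named gene or list called under the chosen settings changed direction while past the threshold under any alternative, and 0 of the genes called were called in the opposite direction. Of the 79 named genes past the test, 18 were not run with both RNAs above background, since their untreated RNA was not well above background on both arrays. Of the 61 run under all 10 alternatives (leaving out saturated probes removed none and is not counted), CCR7 stayed past the test under every one, and 54 under the 8 other than median centring and no filter. S100A8, SPP1, KRT23 and EMP1, among the 18, stayed past it under the 9 of these they were run in. Under those 8, calls lost were BNIP3L, CEBPB, CXCL2 and PPAN with the mean of all probes, CEBPE, HBG1, KLF4, PDGFRB, STX1A and TNFRSF10C with no background correction, and STX1A with both RNAs above background.

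Median centring without loess gave 6 genes higher and 0 lower by limma (219 and 23 at an unadjusted p under 0.05), 542 at least 2-fold higher, 146 at least 2-fold lower and 4318 at least 2-fold in opposite directions, with r = 0.249 across genes. By its construction it leaves any dye difference that varies with intensity. The log ratio of the scanner software gave 1295 higher, 1078 lower, 1456 and 1239 at least 2-fold higher and lower, 132 in opposite directions and r = 0.717. The value table gave 899 lower, 868 at least 2-fold lower and 133 in opposite directions. Shifting the ratios of the chosen settings to the array medians under median centring (1.09 on replicate 1, -1.06 on replicate 2) gave 12 higher and 0 lower. That shift alone thus removed most calls. The like shifts gave 767 higher and 498 lower for the scanner software's log ratio, and 806 and 583 for the value table. These fall short of the counts under those scalings, and no other cause was tested. An offset of 10 gave 103 in opposite directions, and the cause was not tested.

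With no filter on dim probes, which tests 32642 genes, 231 were higher and 35 lower, and r was 0.472. With both RNAs above background, which tests 13117 genes, 535 were higher. With symbols only, which tests 10063 genes, 29 were at least 2-fold in opposite directions and r was 0.647. A threshold of 1.5-fold gave 1844 higher, 1455 lower and 370 in opposite directions. On 1 array alone, a value with no test, the direction of the excess differed. On replicate 1, 1681 genes were at least 2-fold higher and 1924 lower, and on replicate 2, 1872 were higher and 1011 lower.

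Of the gene lists, 0 shifted by camera with an estimated correlation and 0 by fry (0 and 3 at an unadjusted p under 0.05). With the preset correlation, cholesterol synthesis was called in 3 of 9 alternatives, and DNA replication and the unfolded protein list gained a call with no filter on dim probes. The planned comparison of mean with median pixel intensity could not be run, since the scanner files used here give the median pixel signal of the spots. Signal over background limits 162 of the increases to bounds.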

Other observations

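The families in the next paragraphs were picked by name after the results were seen, and so were the tests on the MHC class II genes, the histone genes and centring alone. The germline and modification lists were drawn up after the largest changes were seen, and their tests were set before their results.

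Several families with members among the large increases held further genes that rose. Of 14 granzymes and killer lectin receptors with a probe, which are proteins of cytotoxic lymphocytes, 9 were tested and 6 rose, with a median of 1.96 (1.88 to 4.09 under 5 other scalings, and 0.60 over all 14 with no filter on dim probes). Beside GZMA, GZMB changed by 3.30 ± 0.49 and GZMH by 1.94 ± 0.21, while KLRC4, KLRC2 and KLRC1 rose at least 8.54-fold, at least 5.18-fold and at least 3.87-fold. Of the 9 tested, 3 entered only through the treated RNA, and the probes of KLRC4, KLRC2 and KLRC1 can share signal. NKG7, another gene of cytotoxic granules, had a ratio of 0.03 ± 0.25, and none of the 6 T cell receptor and CD8 subunits with a probe was bright enough to be tested. Of 32 CC chemokines and receptors with a probe 12 were tested and 6 rose, among them the monocyte attractant CCL7 at 3.69 ± 0.20, and CCR3, which rose at least 2.61-fold. In this family 6 of the 12 entered the test only through the treated RNA, so that a rise was favoured by the filter, and with no filter 26 of 32 ratios were positive, with a median of 0.39. Of 20 S100 proteins with a probe 10 were tested, 3 of them only through the treated RNA, and 5 rose, with a median of 1.26 over the 10 and of 0.38 over all 20 with no filter. The genes that rose included S100A2 at 2.22 ± 0.66, S100A10 at 1.52 ± 0.22 and S100A4 at 1.52 ± 0.65. The untreated RNA of CCL7 and S100A2 was above background on 1 array. Of 13 serpins of clade B with a probe 6 were tested and 3 rose (SERPINB3, SERPINB10 and SERPINB4), with a median of 0.78 over the 6 and of 0.041 over all 13 with no filter. Of these 6, 2 entered only through the treated RNA, and the probes of SERPINB3 and SERPINB4 can share signal.

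Among families of the basic machinery, mitochondrial ribosomal proteins had a median of -0.51, with 65 of 76 ratios negative (camera p = 5.91e-08, p = 0.0882 with an estimated correlation). Those that fell were MRPS12, MRPS34, MRPS2 and MRPL12, with MRPS12 at -1.62 ± 0.66 and MRPL12 at -1.41 ± 0.18. Proteasome subunits had a median of -0.51 over 37 genes (p = 5.55e-04, p = 0.155 with an estimated correlation), and PSMB10, an immunoproteasome subunit, fell, at -1.55 ± 0.45. Of 7 RNA polymerase I subunits, which transcribe ribosomal RNA genes, 6 had negative ratios with a median of -0.82 (p = 0.0022, p = 0.196 with an estimated correlation), and POLR1G fell, at -1.80 ± 0.87. Of 13 RNA polymerase II subunits 9 had negative ratios, with a median of -0.19 and no shift past the threshold (p = 0.0848, p = 0.319 with an estimated correlation), and POLR2F fell. Cytosolic ribosomal proteins went the other way, with 69 of 79 ratios positive and a median of 0.32 (p = 0.0014, p = 0.593 with an estimated correlation). Their median was 0.57 on replicate 1 and 0.02 on replicate 2, and 0 rose and 0 fell by limma (2 and 1 at an unadjusted p under 0.05). None of these medians changed sign under the 5 other scalings.

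More genes rose than fell, 66.5% of the calls, a share that under other scalings was 54.6% (the scanner software's log ratio, with 1295 higher and 1078 lower), 55.9% (the value table), 66.8% (no background correction) and 100% (median centring, with 6 calls). The first of these meets the bound set in advance for centring as a cause, at most 55% under at least 1 of them, but these scalings change the background or dye treatment as well. With each array only shifted to its median under each of these scalings, the lowest share was 58%, between the bounds set for that test, so centring cannot be told apart from a true excess. Nor can a detection limit, which hides decreases of silent genes: among genes with both RNAs above background the share was 59.2%, between the bounds set in advance, while calls of at least 8-fold there were 50 increases and 3 decreases (86 and 3 over all genes tested). At an unadjusted p under 0.05 the direction turned with the scanner software's log ratio, 2152 genes higher and 2646 lower, and with the value table, 1904 and 2278. On replicate 1 alone, too, fewer genes were at least 2-fold higher (1681) than lower (1924), unlike on replicate 2 (1872 and 1011). Ratios within an array are relative, so an overall rise of RNA under a deacetylase inhibitor was not tested and stays open.

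MHC class II genes rose together. Signal shared between HLA paralogs could add to the ratios of single HLA genes, yet 3 of the 4 members without an HLA name (CD74, CIITA and IFI30) passed the test and rose at least 2-fold, which argues against it as the whole cause. B lymphocytes in the treated culture are argued against by the B cell genes: of 7 with a probe 0 passed the test, 4 were not above background in the treated RNA, and CD79A, bright in both RNAs, was at -1.21. CD79B, the 1 gene that goes with this explanation, was above background in the treated RNA alone (log2 ratio of 0.72, limma adjusted p = 0.218). The prediction was for at least 3 such genes. CIITA, the activator of these genes, rose by 2.43 ± 0.49. A response of the cells to MS-275 is consistent with these values and remains a hypothesis.

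Histone genes had a median of 0.99 on replicate 1 and 0.09 on replicate 2. A dye effect on the histone probes would show in the difference between the arrays divided by 2, whose median was 0.368, outside the central 95% of 10000 random lists of like signal (-0.225 to 0.139). With 1 array per dye orientation, a dye effect cannot be told apart from a difference between the replicates. More cells in S phase in the treated culture of replicate 1 would raise the DNA replication list on that array. Its median was instead lower there, by a difference of -0.322 on the log2 scale. This difference too lies between arrays of opposite dye orientation, so it cannot decide on S phase. Metallothioneins showed the same kind of difference as the histone genes, with a median of 0.537 for the difference divided by 2.

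Enzymes that modify tRNA and rRNA, or their partners, were among the large decreases: PUS1 at -2.46 ± 0.44, WDR4 at -2.47 ± 0.68 and DUS3L at -2.26 ± 1.25, beside DPH2, which modifies a translation factor, at -2.44 ± 0.08. The hypothesis that tRNA and rRNA modifying enzymes fell as a group was tested without these and MRM1. Of 50 tested genes 7 fell and 0 rose by limma (27 and 0 at an unadjusted p under 0.05), 43 had negative ratios, and the median was -0.83 (-1.07 to -0.78 under the 5 other scalings), with camera p = 1.54e-09 and p = 0.211 with an estimated correlation. PUS7, a pseudouridine synthase, changed by -2.11 ± 1.03, TRMT1, a tRNA methyltransferase, by -1.98 ± 0.15, and METTL1, the partner of WDR4, by -1.92 ± 0.74. The shift may belong with the fall of the ribosome biogenesis list, a link that was not tested.

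TEX19 and PRAME, a tumour antigen that rose at least 13.5-fold, raised the hypothesis that germline genes rose as a group. Without them, 4 of 50 listed genes with a probe were bright enough to be tested and 0 rose or fell by limma (2 and 0 at an unadjusted p under 0.05), while the others stayed below the filter with MS-275 as without it. These 4 are fewer than the 5 set as the minimum for a list test, so whether germline genes rose as a group stays open.

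Some genes that rose are neighbours in the genome, such as ITGAM with ITGAX and CCL2 with CCL7. Over all measured neighbours, 48 pairs both rose, against a mean of 17.5 when calls were shuffled over genes (permutation p = 0.0001, the smallest that 10000 shuffles can give). The hypothesis that neighbouring genes rose together beyond tandem paralogs was tested on pairs without a shared name stem: 28 pairs both rose against a mean of 16.7 and a central 95% of 10 to 25 shuffled pairs (one-sided permutation p = 0.0044). Of the 28 pairs, 5 are known paralogs with different names, such as HBB with HBD and CSF1R with PDGFRB, and the other 23 lie inside the shuffled range. That range still holds paralogs with different names among the other measured pairs, so a rise of neighbours beyond paralogs cannot be told apart from the paralogs. Of neighbours without a shared stem, 13 pairs both fell, against a mean of 5.91 (permutation p = 0.0067).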
